A study of Homo sapiens with 171 samples.

How the data were processed

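The study comprised 171 chromatin immunoprecipitation sequencing samples from human breast cancer cell lines, arranged by their titles in 15 sets. A peak list was deposited for 132 samples, with 1 list per library, and the 39 input samples were not analysed here. The lists were 109 broad peak lists (H3K4me3, H3K4me2, H3K79me2 and KDM5B), 14 narrow peak lists (ER and CTCF) and 9 lists of H3K27ac enhancer regions that name a closest and an overlapping gene for each region. Per the labels, the authors used cutadapt, Bowtie2, SAMtools, Picard and MACS2 with the human build hg19, and no version or setting was stated. The use of the inputs as controls was not stated.

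The deposited peak lists give positions in bp, a score of 10 times the -log10 q, a ratio (fold enrichment over the local background of the same library) and -log10 p and -log10 q values, all made by the authors. The deposited enhancer lists give positions in bp and a rank. No list holds read counts. The names of the lists carry a number of down-sampled reads, which ranged from 5.858 to 29 M and was identical for the libraries of a cell line within a set. This number was taken as the depth. Few reads limit how many peaks a caller can find, so peak numbers and lengths were compared only between libraries of equal depth, except where stated. Scores and ratios were not compared peak by peak between libraries, but peaks with -log10 q of at least 10 (strong peaks) were compared in length and number, and such a threshold depends on the enrichment of each library. The lowest -log10 q in a list differed between sets, down to 0.065, and between libraries of a line, so a list is not a fixed threshold on signal. For H3K4me3 in T47D cells it was 0.32 at day 0 and 0.122, 0.0703 and 0.227 after 2, 7 and 14 days of KDM5-C70. In BT474 cells it was 0.416 and then 0.258, 0.224 and 0.22. It went the other way in FULVR cells (0.118, then 0.122, 0.133 and 0.149).

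Chromosomes 1 to 22 and X were used. Overlapping peaks of all libraries of a comparison were merged into regions, and the covered length (bp of peak inside the region) was computed for each library. The value tested was log2 of the covered length plus 200 bp. For the KDM5-C70 (C70) time courses, regions with a peak in at least 6 of 24 libraries were kept, the mean of days 2, 7 and 14 minus day 0 was taken in each of 6 cell lines, and limma 3.58.1 in R 4.3.3 (moderated with a trended prior) tested the mean over lines against 0, two-sided, with Benjamini-Hochberg adjustment at 0.05. Within a set there were no replicates of a condition outside the knockouts, so the cell line was the replicate. Libraries of a condition in different sets were pooled only in the alternative with added untreated libraries and in that with added lines at day 2. In the latter, the MCF7 changes of different sets were averaged. For the knockouts, regions with a peak in at least 2 of 5 libraries were tested with limma over all 5 libraries, and the lone untreated library was assumed to vary like the knockouts. "Wider" and "narrower" refer to the covered length of a region.

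Total covered length, number of peaks, median width and the share of peaks of at least 4 kb were compared with two-sided exact sign-flip permutation tests over lines, as a family of 4 per mark. Peak counts of ER and covered lengths of KDM5B used the same test over 3 or 4 lines. Enhancer lists were compared by the Jaccard index in bp, with a one-sided exact permutation test over the 280 ways to part 9 lists into 3 groups of 3. Shares of regions were compared with Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and the R package data.table (1.17.8) were used. No confidence interval from counts was computed, since the lists hold none. The 95% intervals of the compound differences rest on the t distribution over 3 lines.

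Named genes and regions followed a rule. In the C70 comparison of each mark, the 15 regions with the largest mean change in each direction were named among those past adjusted p = 0.05 and changed alike in all 6 lines. In the knockouts, the rule took the 10 largest in each direction with no overlap between the groups' values. Between a pair of libraries, the rule took the 5 regions of up to 50 kb with the most length gained and the 5 with the most lost, or, for ER, CTCF and enhancer lists, the 5 peaks of highest authors' score or rank found in 1 list only. Members of 10 gene lists (16 to 25 genes each) were named where they passed a test, or changed in covered length by at least 2-fold between a pair of libraries, after adding 200 bp. These lists were estrogen response, luminal identity, basal and mesenchymal, cell cycle, H3K4 methylation machinery, interferon and antigen presentation, housekeeping, developmental regulators, endocrine resistance and other cell types. A selection of these names is printed. The tests, the lists, the naming rule and the alternatives were chosen before the data were examined, apart from those named as chosen later or as not planned.

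No gene annotation of the build hg19 was at hand, so the planned test of gene lists on promoter windows was not run. Gene names are those the authors gave to the enhancer regions, and a peak or H3K4 region is named only where it overlaps such a region. A region without a name is given by position. In place of the promoter test, and chosen after the files were seen, H3K4 regions inside enhancers of list genes were tested with limma's camera (preset correlation of 0.01, and an estimated correlation) and fry, for lists with at least 3 regions. KDM5A and KDM5B are not among the enhancer genes, so the knocked-out loci could not be examined.

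The fits were tested on simulated data with the observed spread and 200 changed regions, 50 for each change. For C70, 96% of regions widened by 2.00 (log2) and 48% of those widened by 1.00 were recovered in H3K4me3, against 54% and 2% in H3K4me2. For the knockouts, 72% and 28% were recovered in H3K4me3 and 0% in H3K4me2. A second simulation of the knockouts with 1299 (H3K4me3) or 2952 (H3K4me2) regions for each change, added because of that 0, recovered 90.1% and 76.1% in H3K4me3 and 64.4% and 36.1% in H3K4me2. The power of the knockout fit therefore depended on how many regions changed. For C70, false calls were 12 of 108 in H3K4me3 and 3 of 31 in H3K4me2. Each of these shares was above the adjusted threshold, so the C70 calls may hold more false ones than that threshold states. In the knockouts, false calls were 2 of 58 in H3K4me3 in the first simulation. In the second they were 163 of 3932 in H3K4me3 and 165 of 4320 in H3K4me2.

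The alternatives were pseudocounts of 50 and 1000 bp, other filters on the number of libraries with a peak, peaks with -log10 q of at least 10 only, centring on the median change of regions covered before and after (or in all 5 knockout libraries), merging across gaps of 1 kb, leaving out each line or replicate, single days, libraries of the same date tag as day 0, 8 lines at day 2 with C70R and C49R added, the number of peaks in place of the covered length, a robust prior, a replicate block and added untreated libraries.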

Results

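The study profiled histone H3 methylation (H3K4me3, H3K4me2, H3K79me2), the H3K4 demethylase KDM5B, the estrogen receptor (ER), CTCF and H3K27ac enhancers in breast cancer cell lines and lines resistant to therapy. MCF7, T47D and ZR75 are ER-positive luminal lines, BT474 is ER-positive with amplified HER2, and SUM159 lacks ER. C70R, C49R, FULR, FULVR and TAMR are, by their names, cells resistant to KDM5-C70 (C70), KDM5-C49 (C49), fulvestrant (FULR and FULVR) and tamoxifen. C70 and C49 are KDM5 inhibitors used at 10 µM, fulvestrant is an ER degrader used at 10 µM, and estradiol (E2) was given at 100 nM after charcoal-stripped serum (CSS). The labels state these doses for MCF7, C70R, C49R, FULVR and TAMR, and they were taken to hold for FULR, which the labels do not equate with FULVR outright. No C70 dose is stated for BT474, SUM159, T47D and ZR75, so an equal dose across the time courses is not known. The labels do not name the parent of the resistant lines, and lines that share a parent are not independent, which limits every test over lines that counts them with MCF7. The deposited lists comprised 41 H3K4me3, 41 H3K4me2, 25 KDM5B, 10 ER, 9 H3K27ac, 4 CTCF and 2 H3K79me2 libraries. Down-sampled depth ranged from 6.753 M reads (FULVR) to 20 M (MCF7) in the H3K4 time courses. Values are from 1 library each unless an n is given.

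The time courses ask what KDM5 inhibition does to H3K4me3. H3K4me3 peaks covered more of the genome with C70 in all 6 lines. In MCF7, covered length went from 25.4 Mb at day 0 to 37.3 Mb at day 2, 42.4 Mb at day 7 and 42.7 Mb at day 14. T47D went from 20.5 to 33.9 Mb, ZR75 from 26.9 to 39.8 Mb, SUM159 from 25.0 to 34.6 Mb and FULVR from 5.65 to 10.95 Mb by day 14, while BT474 measured 18.9 Mb at day 0 and 19.3 Mb at day 14. Of the 17.8 Mb gained in MCF7 by day 14, 83.4% belonged to peaks that touched a day 0 peak. The share was 60.4% of 15.4 Mb in T47D and 56.5% in FULVR at day 14, and it was below 50% in BT474 at day 7 (44.3%) and in FULVR at day 2 (48.9%). Broad peaks of at least 4 kb made up 1.81% of MCF7 peaks at day 0 and 8.91% at day 14.

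**Figure D1:**
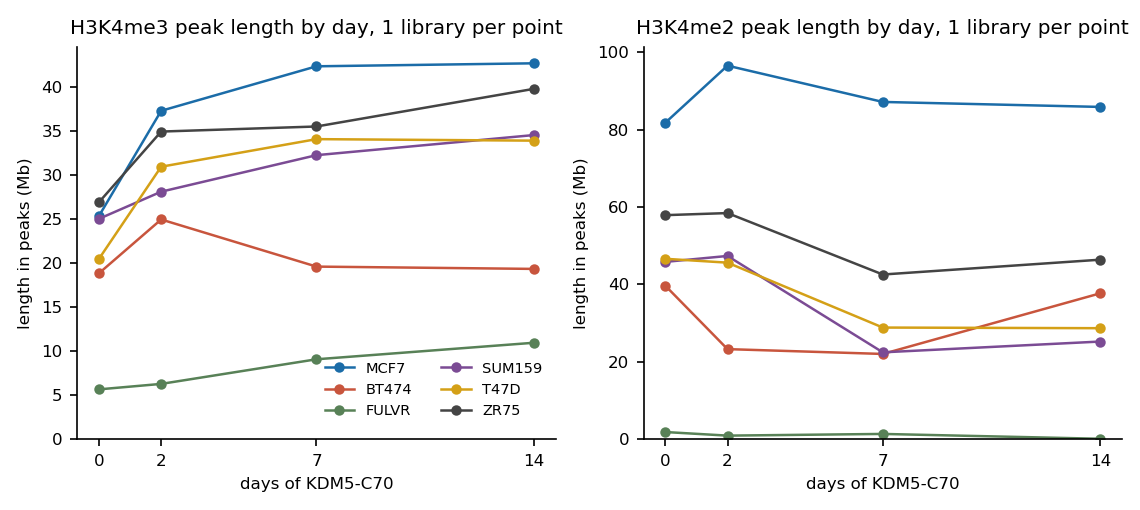
Length of the genome in H3K4me3 peaks (left) and H3K4me2 peaks (right), in Mb, against days of C70, with 1 library per point and a line for each cell line. H3K4me3 in MCF7 runs from 25.4 Mb to 42.7 Mb, while H3K4me2 in T47D runs from 46.6 Mb to 28.7 Mb.

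Averaged over the 3 treated days, H3K4me3 covered length was 1.40-fold that of day 0 (log2 0.48, SD 0.21, n = 6 lines, higher in 6 of 6; exact p = 0.03125, the smallest possible, adjusted p = 0.0625 over 4 measures). The share of peaks of at least 4 kb was higher by 1.94 percentage points (SD 2.26, 6 of 6 lines; exact p = 0.03125, adjusted p = 0.0625). The number of peaks was higher in 5 of 6 lines (log2 0.29, SD 0.16; exact p = 0.0625, adjusted p = 0.0833). The median width differed by log2 0.08 (SD 0.26, 3 of 6 lines; exact p = 0.594). None of the 4 measures passed the adjusted threshold. Untreated MCF7 libraries of 3 sets, of which 2 had 20 M reads and 1 had 16 M, covered 25.4, 22.98 and 28.0 Mb and differed by at most log2 0.29. In peaks with -log10 q of at least 10 alone, the mean turned to -0.60, with 4 of 6 lines higher (exact p = 0.594). That mean came mainly from BT474 (-3.94): in checks chosen later it was 0.06 without BT474 (exact p = 0.875) and -0.25 without the 1 treated library of another date than day 0, BT474 at day 7 (exact p = 0.594).

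By region, 1015 of 21252 H3K4me3 regions were wider with C70 and 0 were narrower (limma, adjusted p under the threshold of 0.05), and 926 of the 1015 were wider in every line. The median change was log2 0.29 over all tested regions and 0.68 over the wider ones. The largest change was in a region of chromosome 20 (45979941 to 45992807) inside an enhancer of ZMYND8, a reader of histone marks, which went from 1669 to 7537 bp on average (log2 2.71, SE 0.50, adjusted p = 0.0366). A region on chromosome 10 (79645255 to 79649328) in an enhancer of DLG5, a scaffold protein of cell polarity, changed by 2.32 (SE 0.42). PIM3, a serine/threonine kinase, changed by 2.00 (SE 0.17, 1243 to 4997 bp), and the immediate early gene IER2 by 1.95 (SE 0.30). TMEM184A (1.91), PRKAR1A (1.71), which encodes a regulatory subunit of protein kinase A, and ZFP36L1 (1.66), an RNA-binding protein of mRNA decay, were also among the 15 largest. The other 8 carried no enhancer gene, such as chromosome 17 from 79301399 to 79305880 (2.63, SE 0.37). Among smaller changes, picked after their values were seen, were MALAT1 (1.45), a nuclear long noncoding RNA, and the antiproliferative gene TOB1 (1.34). The call was fragile. It ended (0 regions) while the median change stayed near 0.29 without MCF7 (0.24), without SUM159 (0.31), without T47D (0.25) and at day 7 alone (0.27), and with a pseudocount of 50 bp (0.37), and 1 region was left without ZR75 (0.30) and 2 at day 2 alone (0.24). It also ended with a median of 0.08 without the filter, 0.05 with each line centred on its median and -0.24 in strong peaks only, whereas 2485 were called without FULVR (0.28).

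The wider regions lay in enhancers more often than other regions did, in a test that was not planned. Of the 1015, 150 (14.8%) overlapped an H3K27ac enhancer of MCF7, C70R or C49R, against 1204 of the other 20237 (5.95%; odds ratio 2.74, Fisher's exact p = 1.2e-22), and 6.24% was expected from regions matched on day 0 length. Overlap was scored over the whole merged region, length gained with C70 included. Merged length was not matched, so part of the difference may come from longer merged regions. Within enhancers, genes of luminal identity had 18 H3K4me3 regions, of which 4 were wider over all regions tested and 10 when adjusted over the list alone. The 4 were at CDH1, which encodes E-cadherin (1.05, SE 0.22, 1756 to 4370 bp, adjusted p = 0.0438), the epithelial transcription factors SPDEF (0.93, SE 0.19) and ELF3 (0.88, SE 0.195), and the luminal keratin KRT19 (1.25, SE 0.28). A second KRT19 region measured 2.19 (SE 0.575, adjusted p = 0.0613), and the longest regions at FOXA1 (0.13) and GATA3 (0.16), with 6247 and 11190 bp covered at day 0, did not pass. Estrogen response genes had 19 regions, of which 1 passed over all regions and 1 over the list alone, at IGF1R, the insulin-like growth factor receptor (0.91, SE 0.15, 1006 to 2200 bp). GREB1, a classical ER target, had 4 regions with changes of 0.39 to 1.42 and adjusted p of at least 0.088. Endocrine resistance genes had 8 regions (1 wider, 4 over the list alone, IGF1R again), and interferon and antigen presentation genes 3 regions (0 wider, 3 over the list alone, at IRF1 and STAT1). The lists with 1 region each, for which adjusting over the list is no adjustment, passed nowhere over all regions: cell cycle (CDC20, 0.41), developmental regulators (SIX1, 0.44), housekeeping (ACTB, 0.49), H3K4 methylation machinery (KMT2D, 0.25), other cell types (SYP, 0.57) and basal and mesenchymal (ZEB1, 0.40). Of all 21252 regions, 6886 were wider at an unadjusted p under 0.05, so passing over a short list alone says little.

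Set against the other enhancer regions, with a median change of 0.45, no list passed. Camera, which makes that comparison, gave adjusted p = 0.401 for luminal identity, endocrine resistance and interferon, and 0.806 for estrogen response. With an estimated correlation, adjusted p = 0.794 for the first 3 and adjusted p = 0.898 for estrogen response. Fry, which asks only whether a list's regions move one way, gave adjusted p from 0.00905 to 0.0106 for these 4 lists.

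**Figure D2:**
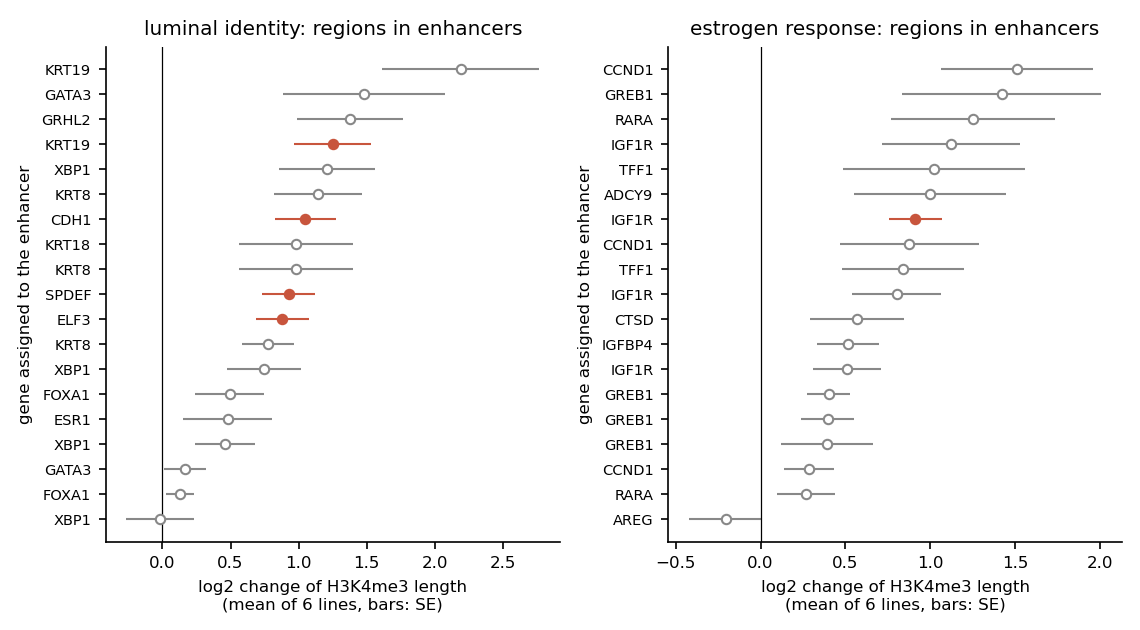
Change of H3K4me3 covered length with C70 (log2, mean of 6 lines, bars are SE) for each region inside an enhancer of a luminal identity gene (left) or an estrogen response gene (right). Filled points passed adjusted p = 0.05 over all 21252 regions, the largest of them KRT19 at 1.25, and a region shared by KRT8 and KRT18 is drawn for each gene.

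KDM5B occupied the wider regions more often than the rest. In untreated MCF7, 904 of the 1015 wider H3K4me3 regions (89.1%) held a KDM5B peak, against 13341 of the other 20237 (65.9%; odds ratio 4.21, Fisher's exact p = 1.65e-62). Wider regions were also longer at day 0 (median 1287 bp against 790 bp). Against regions of similar day 0 length the expected share was 84.3% (odds ratio 1.68, permutation p = 0.0001, the smallest that 10000 resamples can give). Overlap was scored over the whole merged region, length gained with C70 included, and merged length was not matched. Wider regions can therefore meet a KDM5B peak more readily, so the remaining difference does not show a preference for KDM5B sites. With KDM5B of another set the shares were 77.1% and 55.2% (odds ratio 2.74), and with strong KDM5B peaks alone 3.84% and 2.05% (39 of the 1015; odds ratio 1.91, Fisher's exact p = 0.000477). Regions are not independent replicates.

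Averaged over the treated days, H3K4me2 covered less of the genome with C70 in 5 of 6 lines. From day 0 to day 14, its covered length went from 45.8 to 25.2 Mb in SUM159, from 46.6 to 28.7 Mb in T47D, from 57.9 to 46.4 Mb in ZR75 and from 1.82 to 0.0807 Mb in FULVR. FULVR measured 0.895 Mb at day 2 and 1.33 Mb at day 7. The day 14 libraries of FULVR and BT474, and that of BT474 at day 7, were of another date than day 0. BT474 measured 39.6 Mb at day 0, 22.02 Mb at day 7 and 37.7 Mb at day 14, and MCF7 81.8 Mb at day 0 and 85.9 Mb at day 14. Strong H3K4me2 peaks, with -log10 q of at least 10, covered 29.4 Mb in untreated MCF7 and 4.99 Mb on average under C70, and 11.1 and 0.278 Mb in SUM159. The mean change of these strong peaks was log2 -3.75, lower in all 6 lines (exact p = 0.03125, 200 bp added).

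Over all peaks, the mean difference in H3K4me2 covered length was log2 -0.63 (SD 0.72, n = 6 lines, lower in 5; exact p = 0.0625, adjusted p = 0.0833), a difference that missed the threshold. Without FULVR (-1.99) the mean was -0.35 (exact p = 0.125), and at day 2 alone it was -0.25, with 3 of 6 lines higher (exact p = 0.438). The median H3K4me2 peak was narrower in 6 of 6 lines (log2 -0.35, SD 0.12; exact p = 0.03125, adjusted p = 0.0625), and the share of peaks of at least 4 kb was lower in 6 of 6 (-0.96 percentage points, SD 0.67; exact p = 0.03125, adjusted p = 0.0625). Limma called 0 of 53008 H3K4me2 regions wider and 0 narrower, with 2382 wider and 10514 narrower at an unadjusted p under 0.05. Without FULVR, whose lists held 231 to 2605 peaks, 252 regions were wider and 7062 narrower. Centring each line on the median of regions covered both at day 0 and under C70 moved all regions of a line alike, to a median of 0.46, and 10897 were then called wider and 2544 narrower. Enhancer regions had a median of -0.28, while estrogen response genes (30 regions, median 0.03, mean -0.04), luminal identity genes (27 regions, median 0.01, mean -0.18) and endocrine resistance genes (16 regions, median 0.03, mean 0.06) had medians near 0. Single regions differed widely. Luminal identity regions ran from -2.10 at XBP1 (4190 to 1161 bp) to 0.62 at KRT8. Regions at FOXA1 (-1.87, 6006 to 2222 bp) and GATA3 (-0.94) were wider in 0 of 6 lines. Estrogen response regions ran from -1.37 at AREG to 0.93 at STC2. Camera, which compares these 3 lists with other enhancers, gave adjusted p of 0.0732, 0.0874 and 0.0732, and with an estimated correlation adjusted p = 0.188 for each of the 3. The interferon list (3 regions, median -0.43) gave adjusted p = 0.879, or adjusted p = 0.914 with an estimated correlation. Fry gave adjusted p from 0.675 to 0.774 for these 4 lists. The lists with 1 or 2 regions had medians of -0.42 (basal and mesenchymal), -0.59 (cell cycle), -0.50 (developmental regulators), -0.81 (H3K4 methylation machinery), -0.23 (housekeeping) and -1.15 (other cell types). For each of the 10 lists 0 regions passed over all regions (limma). When adjusted over the list alone, 1 region was narrower in the estrogen response list, of 30. The same held for 1 region each of the basal and mesenchymal, developmental regulators, H3K4 methylation machinery and other cell types lists, which had 1 or 2 regions.

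C70 and C49 were compared at 10 µM and 2 days in MCF7, C70R and C49R. H3K4me3 covered more with C70 than with C49 in each line: 30.1 against 18.7 Mb in MCF7, 36.4 against 34.3 Mb in C70R and 36.4 against 30.2 Mb in C49R. Untreated cells covered 22.98, 30.5 and 25.4 Mb. Regions longer with C70 than with C49 included enhancers of KRT7, a luminal keratin, in MCF7 (0 bp with C49 and 6179 bp with C70) and C49R (442 and 6556 bp), RHOU, a Rho family GTPase, in MCF7 (32592 and 40226 bp), and PIM3 in C70R (8457 and 12088 bp). The mean difference was log2 0.35 (SD 0.31, n = 3 lines, 95% interval -0.42 to 1.11; exact p = 0.25, the smallest possible). H3K4me2 measured 21.2 Mb with C70 and 32.9 Mb with C49 in MCF7, 9.61 and 42.4 Mb in C70R, and 77.2 and 76.3 Mb in C49R (mean difference -0.92, SD 1.11, 95% interval -3.67 to 1.83; exact p = 0.5). Limma over the 3 lines, a test chosen after the data were seen, called 0 regions of either mark (unadjusted p under 0.05 for 1650 longer and 23 shorter with C70 in H3K4me3, and 9 and 1080 in H3K4me2). The intervals leave room for no difference and for a large one.

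Knockouts of KDM5A and KDM5B, a pair of libraries each in MCF7, ask which enzyme limits H3K4 methylation. H3K4me2 covered 38.4 Mb in the untreated library, 59.4 and 53.6 Mb in the KDM5A knockouts, and 67.0 and 58.5 Mb in the KDM5B knockouts. H3K4me3 covered 28.0 Mb untreated, 30.7 and 31.6 Mb without KDM5A, and 34.5 and 32.4 Mb without KDM5B. Against the untreated library, limma called 3678 H3K4me2 regions wider and 1 narrower without KDM5B, and 1201 wider and 1 narrower without KDM5A, where the median of all regions moved by 0.63 and 0.47. The spread of the 1 untreated library was taken from the knockouts, and its H3K4me2 covered length differed by log2 -1.09 and -0.67 from untreated MCF7 of other sets (81.8 and 61.3 Mb, at 20 M reads against 16 M), more than these medians, so a peculiarity of that library was not ruled out for the calls or for the genes named from them. The largest named change was at an enhancer of MLPH, which encodes melanophilin (chromosome 2, 238416869 to 238422546; log2 4.42, SE 0.32, adjusted p = 0.0353 without KDM5B, and 3.96, SE 0.32, adjusted p = 0.045 without KDM5A). The untreated library held 0 bp at this region, at the GATA3 and XBP1 regions below and at all of the 10 largest wider regions of either knockout, so the size of these changes depends on the 200 bp added. List genes among the wider calls in the KDM5B knockout were the luminal factors GATA3 (2.51, SE 0.275), XBP1 (2.34, SE 0.27), ESR1 (0.895) and SPDEF (2 regions, 0.52 and 0.53), the estrogen response genes GREB1 (3 regions, 0.69 to 2.56), CCND1 (1.48), RARA (1.11), SIAH2 (1.07) and IGF1R (2 regions, 0.61 and 1.68), and BCAR1 (1.04) and SOX1 (1.55). In the KDM5A knockout they were GREB1 (2.93), XBP1 (2.47), CCND1 (1.27) and SIAH2 (1.11).

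The 1 narrower region was on chromosome 9 (32524409 to 32526483, -1.01, SE 0.14) without KDM5B and on chromosome 8 (9412275 to 9414373, -1.76, SE 0.18) without KDM5A. The knockouts shared 1183 wider H3K4me2 regions, against 93.5 expected from independent lists, but shared the untreated library. Their changes correlated at 0.724 across regions, against 0.665 simulated for unchanged groups with a common control. Between the KDM5B and KDM5A knockouts no H3K4me2 region passed (limma 0 wider and 0 narrower, 4355 and 793 at an unadjusted p under 0.05). H3K4me3 gave 0 regions in each direction in all 3 comparisons (limma, unadjusted p under 0.05 for 4600 wider and 58 narrower without KDM5B, 2801 and 217 without KDM5A, and 1847 and 209 between the knockouts). With untreated libraries of 2 other sets added, 3397 H3K4me3 regions were wider without KDM5B and 895 without KDM5A (5 and 8 narrower), and in strong peaks alone 1181 and 962 (110 and 129 narrower). The added libraries had 20 M reads against 16 M and covered 25.4 and 22.98 Mb of H3K4me3, against 28.0 Mb in the untreated library of the knockout set. All knockouts were in that set, so the 3397 and 895 calls cannot be told apart from a difference between sets. In H3K4me2 those added libraries left 0 calls and medians of 0.28 without KDM5B and 0.13 without KDM5A. Leaving out either KDM5A library or the first KDM5B library also gave 0 calls in the KDM5B comparison, with medians of 0.63, 0.63 and 0.49, and leaving out any 1 knockout library gave 0 in the KDM5A comparison, with medians of 0.30 to 0.48.

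The H3K4me3 changes with C70 and with the KDM5B knockout in MCF7 were weakly related across 21993 regions (Pearson 0.168, Spearman 0.110, covariance 0.0459). The sign was the same in 76.9% of regions, against 75.9% expected from the share of each sign if the changes were unrelated. For the KDM5A knockout Pearson's r was 0.0987 (Spearman 0.0569; same sign in 67.2%, 65.1% expected), and with 2 days of C70 from another set it was 0.0415 (Spearman 0.00822; 68.4%, 59.9% expected). Regions are not independent replicates.

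ER binding was compared 45 min after E2 in MCF7, C70R and C49R. ER peaks numbered 1629 without and 10279 with E2 in MCF7, 4581 and 11218 in C70R, and 3082 and 14629 in C49R, at 15 M reads each. In enhancers of estrogen response genes, ER peaks went from 8 to 32 in MCF7, from 15 to 34 in C70R and from 12 to 34 in C49R, and in those of luminal identity genes from 11 to 29, from 25 to 36 and from 14 to 40. IGF1R enhancers went from 1 to 8 peaks in MCF7, GREB1 from 1 to 7, CCND1, a cell cycle driver, from 0 to 4, and FOXA1, the ER pioneer factor, from 0 to 4. In C70R, FOXA1 already held 3 ER peaks without E2 and reached 6. Basal and mesenchymal, housekeeping, cell cycle, developmental, other cell type and H3K4 methylation machinery lists had 0 ER peaks in their enhancers in these 3 lines, and the interferon list had 1, at IRF1 in C70R with E2. Each of these lists had only 1 or 2 genes with an enhancer, against 11 for estrogen response and 12 for luminal identity. Their low counts therefore say little about where ER binds. The strongest peak lists differed at sites such as an enhancer of the keratin KRT80 in C49R (chromosome 12, 52542271 to 52543158), found with E2 only. The mean ratio was 4.19-fold (log2 2.07, SD 0.70, higher in 3 of 3 lines; exact p = 0.25, the smallest possible). Of the peaks seen without E2, 79.6% in MCF7, 87.9% in C70R and 65.7% in C49R were found again with E2.

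In FULR cells, ER peaks numbered 15409 untreated, 6263 with fulvestrant, 3679 with C70 and 2599 with both, at 20 M reads. ER peaks in luminal identity enhancers numbered 48, 26, 22 and 13, and in estrogen response enhancers 22, 12, 10 and 7. FOXA1 went from 8 to 3, 2 and 1 peaks, GATA3, a luminal transcription factor, from 6 to 3, 2 and 0, RARA from 8 to 4, 2 and 1, and ESR1, the gene of ER itself, from 3 to 0 under each treatment. TFF1, a classical ER target, had 4 peaks untreated and 3, 3 and 2 under treatment. Of the peaks left under C70, 83.8% were among those of untreated cells, against 67.7% under fulvestrant and 61.7% under both. There were no replicates, so no test was made.

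KDM5B after 45 min of E2 was compared in 4 lines at 5.858 M reads. KDM5B covered length went from 2.87 to 5.88 Mb in MCF7 and from 1.15 to 5.51 Mb in C70R, from 1.18 to 0.196 Mb in FULR, and stood at 0.128 and 0.138 Mb in TAMR. In MCF7, KDM5B was longer with E2 at enhancers of GATA3 (3137 to 13570 bp), RARA (0 to 2825 bp) and TFF1 (0 to 3053 bp), and at IRS1, an adaptor of insulin signalling (1174 to 5042 bp). In C70R it was longer at FOXA1 (980 to 7226 bp) and GATA3 (1864 to 9566 bp), whereas in FULR no KDM5B peak was left at FOXA1 (2486 to 0 bp) and GATA3 (915 to 0 bp). The mean change was log2 0.20 (SD 2.06, higher in 3 of 4 lines; exact p = 0.875, smallest possible 0.125) and turned negative without MCF7 (-0.08), without C70R (-0.48) or with peak numbers (-0.08).

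C70 for 5 days was compared with untreated cells for KDM5B in 3 lines. KDM5B covered 20.2 Mb untreated and 33.1 Mb with C70 in MCF7, 13 and 36.0 Mb in C70R, and 11.3 and 14.1 Mb in FULR. Untreated KDM5B of another set, at 20 M reads against 16 M, covered 12.6 Mb in MCF7 and 14.7 Mb in C70R, so untreated MCF7 libraries differed about as much as MCF7 did with C70. In C70R, estrogen response enhancers held 9628 bp of KDM5B peak untreated and 57896 bp with C70, and luminal identity enhancers 26745 and 71658 bp. GREB1 went from 1436 to 18347 bp, IGF1R from 1639 to 12010 bp, TFF1 from 2432 to 12198 bp and KRT8, a luminal keratin, from 1784 to 12835 bp. In FULR, luminal identity enhancers held 12696 and 36588 bp, with GATA3 at 6065 and 15283 bp. In MCF7 they held 42725 and 52934 bp, and IGFBP4 went from 1349 to 0 bp. The mean change was log2 0.83 (SD 0.59, 1.78-fold, higher in 3 of 3 lines; exact p = 0.25, the smallest possible). By number of peaks it was 0.52 (exact p = 0.5), and FULR had 26804 peaks untreated and 21127 with C70. The share of KDM5B peaks on untreated H3K4me3 was 41.4% and 28% with C70 in MCF7, 55.2% and 35.2% in C70R, and 23.5% and 60% in FULR (H3K4me3 of CSS cells). The number of KDM5B peaks on it was 13800 and 15295 with C70 in MCF7, 11888 and 17240 in C70R, and 6286 and 12676 in FULR. The lower shares in MCF7 and C70R therefore came with more peaks off H3K4me3, not fewer on it.

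**Figure D3:**
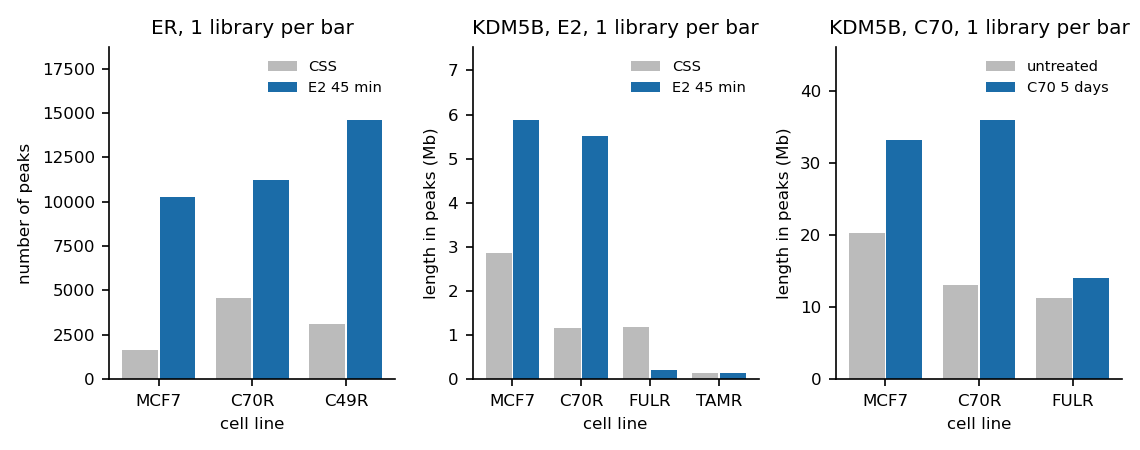
Number of ER peaks with and without E2 (left) and length in KDM5B peaks in Mb with E2 (middle) or C70 (right), by cell line, with 1 library per bar. ER peaks in C49R stand at 3082 and 14629, and KDM5B in FULR stands at 1.18 Mb without and 0.196 Mb with E2.

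KDM5B in MCF7 also differed between growth media, at 17 M reads. It covered 1.277 Mb in CSS, 6.31 Mb in CSS with E2, 5.27 Mb in CSS with insulin and 5.09 Mb in full serum. In CSS with insulin, FULR covered 3.31 Mb and TAMR 4.01 Mb. At 20 M reads in another set, untreated MCF7, C70R and C49R covered 12.6, 14.7 and 19.4 Mb. In FULR, fulvestrant gave 6.36 Mb against 11.3 Mb untreated, and C70 with fulvestrant 18.1 Mb. TFF1 enhancers held 224 bp of KDM5B peak in untreated FULR, 0 bp with fulvestrant, 1245 bp with C70 and 2206 bp with both.

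The enhancer lists ask whether resistance or treatment reshaped H3K27ac enhancers. MCF7 had 1284 untreated, 995 with C49 and 1008 with C70, C70R had 695, 627 and 661, and C49R had 918, 499 and 770. Lists of the same line overlapped more (mean Jaccard index 0.57) than lists of different lines (0.43; one-sided exact permutation p = 0.00357, the smallest possible), and lists of the same treatment did not (0.438 against 0.474; one-sided exact permutation p = 0.775). The index cannot exceed the ratio of the shorter list to the longer. The lists covered 1.40 to 1.965 Mb in MCF7, 0.726 to 0.804 Mb in C70R and 0.597 to 1.231 Mb in C49R. The lower index between lines therefore also reflects length. The mean over lines did not hold for C49R, whose lists shared 0.397 to 0.531 with each other and 0.444 to 0.573 with those of C70R, and untreated C49R shared 0.542 with MCF7 under C49. Of 1746 merged enhancers, 336 were in all 9 lists. GATA3, FOXA1, XBP1, KRT8, GRHL2, CCND1, IGF1R and ADCY9 had an enhancer in every list, as did KMT2D of the H3K4 methylation machinery and the housekeeping gene ACTB. In MCF7 alone were 69 enhancers present under all 3 conditions, the most of any of the 84 ways to pick 3 lists (highest other 10), among them those of ATP9A, NRP1, a site near ELF3 and the microRNA gene MIR21. The MCF7 lists were also the 3 longest, which favours this count. C70R alone had 4 (highest-ranked LINC00910) and C49R alone 7, led by TBX2, a T-box transcription factor at rank 2.

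Genes of the fixed lists were counted in each line, without a test. Of 11 estrogen response genes with an enhancer, 8 were in all 3 MCF7 lists, 4 in all 3 of C70R and 5 in all 3 of C49R, and of 12 luminal identity genes, 8, 7 and 5, beside shorter lists in C70R and C49R (695 and 918 enhancers untreated, against 1284). In any list of a line, luminal identity genes numbered 10 in MCF7, 9 in C70R and 10 in C49R, with KRT19 in C70R and TFAP2C in C49R but not in MCF7. IGFBP4 and STC2 had none in C70R or C49R, and KRT18 none in C70R. In untreated cells, enhancers present in C70R and not in MCF7 included those of RHOU (rank 1) and ID2, an inhibitor of differentiation (rank 65), and the highest-ranked of MCF7 and not of C70R was PVT1 (rank 15 in MCF7). An enhancer of CDH1 (rank 66 in untreated MCF7) was absent from MCF7 with C49 and with C70.

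**Figure D4:**
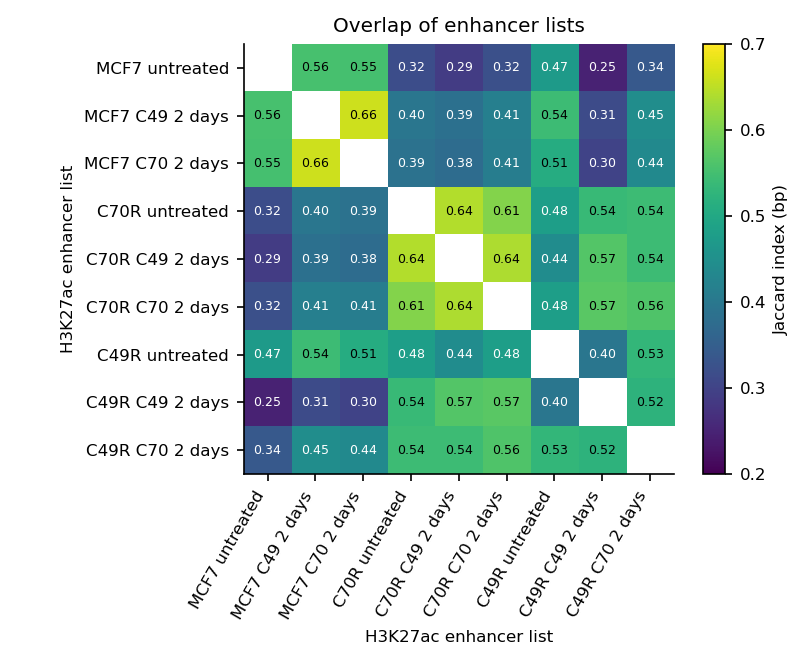
Overlap of the 9 H3K27ac enhancer lists as the Jaccard index in bp (colour and number), from 3 cell lines and 3 conditions. The C70R lists share 0.607 to 0.642 with each other, and untreated MCF7 shares 0.318 with untreated C70R.

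Fulvestrant- and tamoxifen-resistant cells were compared with MCF7 in CSS at 20 M reads. FULR covered less H3K4me2 (37.3 against 56.8 Mb) and H3K4me3 (25.4 against 30.6 Mb) than MCF7, and TAMR covered 43.7 and 31.1 Mb. Covered length was also summed over the enhancers of list genes. These enhancers came from H3K27ac lists of MCF7, C70R and C49R only, so sites particular to FULR or TAMR were not counted. H3K4me2 at estrogen response enhancers was 66639 bp in MCF7, 30507 bp in FULR and 35533 bp in TAMR. At luminal identity enhancers H3K4me2 was 108826, 85903 and 90637 bp. Within enhancers of single genes, H3K4me2 was as follows. GREB1 had 11936, 1574 and 1283 bp, IGF1R 19371, 7760 and 7256 bp, and ESR1 1907, 0 and 717 bp. A region of 8245 bp at GREB1 (chromosome 2, 11679242 to 11687486) had no peak in FULR or TAMR. In H3K4me3, GREB1 had 6205, 1427 and 1151 bp, while KRT19 had 911 bp in MCF7, 247 bp in FULR and 2937 bp in TAMR, and SPDEF went from 1347 bp in MCF7 to 3074 bp in TAMR. With 1 library per line, no test was made.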

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

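The sign flips and the tests on strong peaks in this part were chosen after the results were seen.

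H3K4me2 moved in different directions by line, and these differences were not tested. With C70 at days 2, 7 and 14, covered length was above day 0 on each day in MCF7 (mean log2 0.13) and below it on each day in BT474 (-0.56), FULVR (-1.99) and T47D (-0.48). The FULVR mean rests largely on day 14 (0.0807 Mb, against 0.895 Mb at day 2 and 1.33 Mb at day 7). The day 14 libraries of FULVR and BT474, and that of BT474 at day 7, were of another date than day 0. After 2 days of C70 in the other set the change in covered length was -1.53 in MCF7, -1.95 in C70R and 0.27 in C49R, so MCF7 itself went opposite ways in 2 sets. With C49, H3K4me2 measured -0.90 in MCF7, 0.19 in C70R and 0.25 in C49R, and H3K4me3 -0.30, 0.17 and 0.25. KDM5B with E2 measured 1.04 in MCF7, 2.26 in C70R and 0.10 in TAMR against -2.59 in FULR. CTCF peak numbers, by the titles, measured 1.02 in MCF7 and -0.89 in FULVR with C70. Each value rests on 1 library per condition, or on 3 treated libraries in the C70 time courses.

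A line stood far from the others in 3 of 9 groups examined, where chance gives about 1 in 20 for each group. Most groups were related measures of the same lists, so they were not independent and 3 of 9 can overstate the excess. SUM159 had a change in the number of H3K4me3 peaks of -0.0116 with C70, against 0.30 to 0.49 in the other 5 lines. FULVR had changes of -1.99 in H3K4me2 covered length and -1.67 in the number of H3K4me2 peaks. Both rest largely on its day 14 library, which was of another date than day 0. That library held 231 peaks (0.0807 Mb), against 1310 (0.895 Mb) at day 2 and 1821 (1.33 Mb) at day 7. FULVR had the fewest reads of the 6 lines (6.753 M) and 2605 H3K4me2 peaks at day 0.

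The first pattern is the longer H3K4me3 with C70. Of 32 sign flips of the 6 lines, only the real one called 1015 wider regions (highest other 0). A share of 1 in 32 is the smallest that 6 lines allow. It argues against chance as the source of that count if the lines are independent, but does not exclude it. Libraries of a line were down-sampled to equal reads, so a difference in reads before that step was not tested. That weak peaks were called more readily in the treated libraries may account for part of the pattern: strong peaks covered more than at day 0 in 10 of 18 treated libraries, 3 of 3 in MCF7 and SUM159, 2 of 3 in FULVR and T47D and 0 of 3 in BT474 and ZR75, though FULVR had only 0.000994 Mb of them at day 0. That count leaves it open, beside a biological response to C70.

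The second pattern is the longer KDM5B with C70. Strong KDM5B peaks covered more with C70 in 2 of 3 lines (log2 3.08 in C70R and 2.20 in FULR, and -0.17 in MCF7), and by number of peaks the mean change was 0.52. That weak peaks were called more readily in the treated libraries may account for part of the pattern and stays open with these 2 of 3 lines, as does a difference in reads before down-sampling. No biological explanation was tested.

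The other counts of called regions decide little. For H3K4me2 with C70, the real count was 0 (highest other 0), and a count of 0 makes all 32 of 32 splits as large whatever the data, so it says nothing about chance. For C70 against C49 there are only 4 splits of 3 lines, too few for a share under 0.05. All 4 gave the real count of 0 in H3K4me3, and all 4 the real count of 0 in H3K4me2 (highest other 0 in both).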

How the results depend on the processing

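Of 226 alternatives, 204 were planned: 134 gave the same result, 28 were weaker, 18 stronger, 20 moved and 4 reversed. For tests, the same result meant the same direction on the same side of the threshold. For counts of called regions it meant an equal or similar count. Many such counts had no called region before or after, so they had no direction to keep and show little about robustness. Of the alternatives chosen after the data were seen, 11 gave the same, 1 was weaker, 3 stronger, 1 moved and 6 reversed. The cause was not tested unless stated. The planned promoter-window test of gene lists, with its alternatives, was not run for want of an hg19 annotation. The KDM5B lists with E2 (5.858 M) and the FULVR time courses (6.753 M) had the fewest reads, and absent peaks there do not show absent binding.

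H3K4me3 regions wider with C70 (1015) numbered 0 with a pseudocount of 50 bp, 3008 with 1000 bp, 0 with no filter, 2189 with a peak in 12 of 24 libraries, 0 in strong peaks (median change -0.24) and 0 with centring, which moves all regions of a line alike. Days 2, 7 and 14 alone gave 2, 0 and 631, libraries of the day 0 date 1935, 8 lines at day 2 2870, and leaving out each line 0 to 2485. Centring without FULVR, chosen later, gave 72. Narrower regions (0) numbered 0 to 1 leaving out each line and 1 with 8 lines. Merging across 1 kb gave 1087 and a robust prior 963.

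H3K4me2 regions wider and narrower with C70 (0 and 0) numbered 14 and 3157 with 1000 bp, 10897 and 2544 with centring, 1 and 1843 with 8 lines, 0 to 252 and 0 to 7062 leaving out each line, and 6628 and 7046 with centring without FULVR.

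For the knockouts in H3K4me3 (0), strong peaks gave 1181 regions wider and 110 narrower without KDM5B and 962 and 129 without KDM5A, and added untreated libraries 3397 and 5, and 895 and 8. The added libraries were of other sets and of another depth than the knockouts. In H3K4me2, regions wider without KDM5B (3678) numbered 8267 with 50 bp, 0 with 1000 bp, 847 with no filter, 1720 in strong peaks (79 narrower), 681 with centring, 0 with added untreated libraries and 0 to 2533 leaving out each library. Those without KDM5A (1201) numbered 4928, 0, 0, 166 (4 narrower), 397, 0 and 0 to 0. KDM5B against KDM5A (0) gave 1927 wider and 982 narrower in strong peaks and 0 to 2373 leaving out each library.

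H3K4me3 covered length (log2 0.48) reversed to -0.60 in strong peaks, mainly by BT474. In checks of strong peaks chosen later it was 0.064 without BT474, -0.83 without MCF7, -0.80 without FULVR, -0.75 without SUM159, -0.79 without T47D, -0.51 without ZR75 and -0.25 without the library of another date. It was 0.44 to 0.55 leaving out each line, where 5 lines cannot give an exact p under 0.0625. The number of peaks gave 0.29 and the median width 0.084. H3K4me2 covered length (-0.63) was -3.75 in strong peaks (-3.30 without libraries of another date, chosen later), -0.35 without FULVR, -0.25 at day 2 alone and -0.24 by number of peaks, and the median width gave -0.35. KDM5B with E2 (0.20) ranged from -0.48 to 1.13 leaving out each line, reversed without C70R (-0.48) and without MCF7 (-0.08), and was -0.076 by peak number. The correlation of C70 with the KDM5B knockout (0.168) was 0.219 with 1000 bp, 0.0987 for KDM5A and 0.0415 with the other C70 set, where a difference over 0.05 was the chosen bound. ER with E2 and C70 against C49 kept their direction under every alternative run. The share of ER peaks found again was 77.8%, and 46.2% when 0.5 of each peak had to overlap.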

Other observations

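H3K79me2, a mark of transcribed gene bodies, was profiled in MCF7 before and after 2 days of C70, at 29 M reads. It covered 76.4 Mb untreated and 63.5 Mb with C70, in 84449 and 91310 peaks. CRIP2, a LIM domain gene, went from 2362 to 5910 bp in 1 region, and PRRC2B from 40049 to 32442 bp. The Jaccard index of the lists was 0.49. CTCF, an insulator protein, had 11526 peaks in the MCF7 library titled untreated and 23285 in that titled C70, and 10261 and 5542 in FULVR, at 15 M reads. The treatments given in the other label fields of these 4 libraries contradict their titles, so the direction depends on which field is right. In MCF7, 92.4% of the smaller list was found in the larger, and in FULVR 92.2%. A CTCF peak at SCYL1 (chromosome 11, 65308266 to 65308627) was found only in the MCF7 list titled C70.

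The tests of the following hypothesis were chosen after the result was seen, apart from that of the strongest and weakest peaks. H3K4me2 may be lost under C70 mainly where H3K4me3 lies. Within 10 classes of day 0 peak strength, the share of H3K4me2 length kept at H3K4me3 peaks minus that elsewhere was -27.9 percentage points on average (SD 10.4, below 0 in 5 of 5 lines, from -17.5 in SUM159 to -39.7 in BT474). Without matching it was below 0 in 4 of these 5 lines (-16.8 to -38.2), 0.629 in MCF7 and 20.4 in FULVR, which had 129 such peaks at day 0 and was left out, a choice made after its total change was seen. Poor enrichment of the treated libraries stays open: it would spare strong peaks, and the strongest 10% of peaks kept 10.2 points more than the weakest 10% on average (SD 23.3 over 5 lines), a mean that comes from MCF7 (51.7), while BT474 (0.926), SUM159 (0.536), T47D (-3.25) and ZR75 (1.002) lay near 0.

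The same measure gave -31.5 (MCF7), -20.4 (C70R) and -14.1 (C49R) with C70 in the other set, and -20.0, -10.7 and -3.18 with C49. Without matching, these were 1.75, 0.0638 and -2.38 with C70 and 14.97, 8.21 and 8.94 with C49, so the sign changed with matching by peak strength in 5 of these 6. Between untreated MCF7 libraries of different sets the matched value was -0.840, 4.66 and 15.2 (33.5, 44.9 and 51.2 without matching), and for the 4 knockout libraries 6.54 to 12.1. These background values come from MCF7 alone. No mechanism was tested for the -27.9 points, nor loss of H3K4me2 signal for a technical reason beside H3K4me3.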
